A study of Homo sapiens with 6 samples.

How the data were processed

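RNA editing was measured by RNA sequencing of HEK293T cells, a transformed human embryonic kidney line, 24 h after electroporation of 1500 ng of plasmid. Per the labels, each library came from cells given either the Cas9 nickase without a deaminase (nCas9) or 1 of 5 adenine base editors, proteins that join the nickase to an evolved TadA adenosine deaminase. The editors were ABE8e, ABE8eW (ABE8e with the V106W substitution in TadA-8e), ABE8eWQ, ABE8s (ABE8.17-m per the labels) and ABE8sQ. The labels do not spell out what Q stands for. The design held 6 libraries with 1 per group and no replicates, so no test across conditions was possible and every value describes single libraries. Polyadenylated RNA was made into stranded libraries, per the labels' protocols.

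The submitters' processing notes name BWA, SAMtools and GRCh38, without versions or roles. The deposited tables list, per the file headers, the read bases of quality 30 or more at each covered position, and their regions are RefSeq transcripts, so positions are transcript positions. The coverage and the 4 base values at each position are raw counts deposited by the authors, and the 4 values summed to the coverage at every position. The deposited frequency is a fraction rounded by the authors to whole hundredths, and was used only to check the counts. It matched the most common changed base over the sum of that base and the reference base. The deposited mean quality is a score and read 37 at every position. Filters on mapping quality, duplicate removal and the handling of reads shared by several transcripts are not given in the sources used here. Mitochondrially encoded mRNAs were not analysed here, nor were introns, apart from those covered by 1 RPL10A transcript.

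The read bases per library numbered 1746030758 for nCas9, 1758047313 for ABE8e, 1852067052 for ABE8eW, 1437071013 for ABE8eWQ, 1770288499 for ABE8s and 1847310802 for ABE8sQ. They lay over 35904 to 40850 transcripts. Coverage was concentrated in genes with few isoforms: genes with 1 RefSeq transcript held 76.1% of the read bases of coding genes, and genes with 5 or more held 4.77%. Genes with near-identical relatives are uncertain.

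The A-to-G share was G over A plus G reads, summed over adenosines of the transcript strand with at least 10 reads in each of the 6 libraries. Sites with at least 10% G in all 6 libraries were left out as shared variants or shared endogenous editing. C-to-T and the other substitution types were treated alike as an error background. Shares carry Wilson 95% intervals, which cover counting error only, since sequenced reads without molecular identifiers are not independent molecules. A wider 95% interval came from 1000 resamples of 6549 genes and describes the spread among genes, not among cultures. Comparisons of editors used ratios of shares after subtraction of the nCas9 share, or of counts after subtraction of the nCas9 count. Edited adenosines had at least 10% G and 2 G reads after each site was thinned to the lowest depth of the 6 libraries, with a fixed seed. A one-sided Fisher's exact test with Benjamini-Hochberg adjustment at 0.05 compared each site in an editor library with the nCas9 library, once for a higher and once for a lower share, and compares those libraries, not the conditions.

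Of 61668 transcripts, 33289 matched the RefSeq gene table by accession and version, 14543 by accession with another version, and 13836 had no match and no gene name. Transcripts were placed on GRCh38 and given coding parts by matching their reference bases to GENCODE 29, which succeeded for 25165 transcripts, 18598 of them with a complete coding part. For regions and codons, each gene was represented by its matched transcript with the longest coding part, as this annotation release carries no canonical tag, and 78.1% of the adenosines received a region. Gene shares were computed for 2936 coding or long non-coding genes with at least 20 such adenosines and 5000 reads in each library. Named genes were the 20 with the largest ABE8e minus nCas9 difference, the 5 largest for each other editor, and the 5 largest differences in each direction for the V106W and Q comparisons. Named sites had at least 50 reads in each library and at most 1% G in nCas9, with 1 per gene, and were the 10 highest in ABE8e and the 5 highest in each other editor. From each gene list the 2 to 4 members with the most reads were eligible to be named.

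The 22 gene lists covered ADAR recoding targets, ribosomal proteins, mitochondrially encoded mRNAs, long non-coding RNAs, nuclear-encoded oxidative phosphorylation subunits, histones, proto-oncogenes, tumour suppressors, cytosolic chaperones, the unfolded protein response, interferon response, p53 targets, immediate early genes, glycolysis, translation factors, splicing factors, tRNA and RNA deaminases, base excision and mismatch repair, and fibroblast, leukocyte, hepatocyte and keratinocyte markers. Lists with at least 3 measured members were placed as percentiles among 10000 random lists of the same size matched on reads. Gene coverage was the mean depth per gene scaled by the library total, as a log2 ratio to nCas9, for 2474 genes.

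The groups, designs, gene lists, naming rules and alternative settings were fixed before the data were examined. The alternatives were depth minimums of 20 and 50 reads, no site left out, sites with 1% or more G in nCas9 left out, each library's own sites, exon boundaries left out, unweighted means, other thresholds for edited adenosines, no thinning, edited adenosines only for sequence context, and another scaling of coverage. A comparison of coverage, of genes and of gene lists, with the mean of the other 4 editors was added after seeing the data. The calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, Biopython 1.88, ViennaRNA 2.7.2 and Matplotlib 3.10.9. They were tested on simulated data of 300000 sites. For ABE8e against nCas9, the 10% rule recovered 47% of sites simulated at 10% G and 90.5% of those at 20% G, and the Fisher test recovered 28.5% and 47.5%, with 0 false calls among 331. The simulation drew independent reads with the same background at every unchanged site. It therefore says little about false calls in the real libraries, whose background differs between sites. The counting interval of a ratio of shares held the known ratio in 942 of 1000 simulated runs, while the resampling of genes was not tested in this way. In the list test, 11 of 200 unchanged lists fell outside the middle 95%, and 200 of 200 raised lists lay above it.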

Results

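Transcriptome-wide adenosine and cytidine substitution was compared among 6 HEK293T libraries, 1 for nCas9 and 1 for each of the editors ABE8e, ABE8eW, ABE8eWQ, ABE8s and ABE8sQ. The A-to-G measurements covered 1504287 adenosines that were read in every library. These sites held 435826341 A or G reads in nCas9, 438188841 in ABE8e, 460072257 in ABE8eW, 354421641 in ABE8eWQ, 437838029 in ABE8s and 456388977 in ABE8sQ. With 1 library per group, differences in plasmid uptake or editor expression between cultures could not be separated from differences between editors.

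The first comparison asked how much each editor deaminated cellular RNA. In nCas9, 0.0413% of reads at adenosines carried G. The share was 0.729% in ABE8e, 0.426% in ABE8eW, 0.0626% in ABE8eWQ, 0.973% in ABE8s and 0.0777% in ABE8sQ. These shares were 17.7-fold (16.4 to 18.9, gene resampling), 10.3-fold (9.63 to 11.04), 1.52-fold (1.47 to 1.57), 23.6-fold (22.1 to 25.1) and 1.88-fold (1.77 to 1.99) that of nCas9. Each editor lay above nCas9 on 23 of 23 chromosomes, which are not replicates. The Wilson intervals, from 0.0411 to 0.0415% in nCas9 and from 0.728 to 0.729% in ABE8e, were far narrower than the spread among genes. With no site left out the shares of nCas9, ABE8eWQ and ABE8sQ rose to 0.0825%, 0.126% and 0.131%, and as an unweighted mean of sites the nCas9 share was 0.0642%.

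The count of edited adenosines, those with at least 10% G after thinning, was 1315 in nCas9, 16719 in ABE8e, 7136 in ABE8eW, 1397 in ABE8eWQ, 21005 in ABE8s and 1498 in ABE8sQ. The median depth per thinned site was 43 reads. The count depended on the threshold: at 5% G it was 43500 in ABE8e and 58834 in ABE8s, and at 50% G it was 118 in ABE8e, above the 101 of ABE8s. Fisher's exact test against nCas9 found 49848 adenosines with a higher G share in ABE8e, 22883 in ABE8eW, 311 in ABE8eWQ, 72534 in ABE8s and 1085 in ABE8sQ, at an adjusted p below 0.05. The same test run in the opposite direction found no adenosine with a lower share in any of the 5 libraries. Few sites carried enough G in nCas9 for a fall to pass, so this result says little about lower shares. By the 10% rule, 979 adenosines were edited in nCas9 and not in ABE8e, and 969 in nCas9 and not in ABE8sQ. The test found over 1.5 times as many sites as the 10% rule in ABE8e, ABE8eW and ABE8s, and fewer in both Q libraries. Among 697027 adenosines with at least 50 reads in each library, 1.26% had 1% or more G in nCas9. The figure was 23.1% in ABE8e, 14.1% in ABE8eW, 1.88% in ABE8eWQ, 31.1% in ABE8s and 1.93% in ABE8sQ.

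Editing was spread over nearly all measured transcripts in the libraries without Q. Of 2936 genes, 2922 had a higher G share in ABE8e than in nCas9, 2889 in ABE8eW, 2225 in ABE8eWQ, 2930 in ABE8s and 2398 in ABE8sQ. The median gene share was 0.0384% in nCas9, 0.599% in ABE8e, 0.343% in ABE8eW, 0.0553% in ABE8eWQ, 0.812% in ABE8s and 0.0623% in ABE8sQ.

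The genes with the largest ABE8e minus nCas9 difference included several known stress-response and immediate early genes. SESN2, a p53 target that restrains mTORC1, led with 8.78% G in ABE8e (Wilson interval 8.43 to 9.13) and 0.0158% in nCas9. DNAJB1, an HSP40 co-chaperone, followed with 7.29%, IER2 with 7.06%, HMOX1, the inducible heme oxygenase, with 6.98%, and BAG3, a co-chaperone of HSP70, with 6.80%. TNFRSF12A, the receptor of TWEAK, stood at 6.70%, PPP1R15A, a stress-induced regulatory subunit that directs eIF2α dephosphorylation, at 6.59%, and DUSP1, a MAP kinase phosphatase, at 6.47%. EGR1, an immediate early transcription factor, had 5.54% and HSPA6, an inducible HSP70, had 4.97%. Non-coding host genes were among them too, with 5.76% in EPB41L4A-AS1, 5.56% in SNHG15 and 5.54% in SNHG11. The rest of the 20 were SELENOW, MSX1, ISL2, KANSL2, DDIT4, ITGA5 and PIM3, between 4.19% and 4.80%.

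In the nCas9 library these 20 genes lay between 0.0158% and 0.0922%. All of the 20 were lower in ABE8eWQ and ABE8sQ than in the matching editor without Q: in ABE8eWQ the highest was SNHG15 at 0.41%, and in ABE8sQ the highest was EPB41L4A-AS1 at 0.181%. At the other end, NORAD, an abundant long non-coding RNA, carried 0.0807% in ABE8e against 0.0373% in nCas9, and the splicing factor transcript HNRNPA1 carried 0.121% against 0.0503%. KCNQ1OT1 and TIGD1 carried 1.13% and 1.21% G in nCas9 already. They reached 1.499% and 1.58% in ABE8eWQ, so part of their share there was background.

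Among the gene lists, immediate early genes and cytosolic chaperones stood highest. The 5 measured immediate early genes had a median of 5.54% in ABE8e, 4.24% in ABE8eW and 4.81% in ABE8s, each at percentile 100 of the matched random lists. Their medians were 0.158% in ABE8eWQ (percentile 99.95) and 0.116% in ABE8sQ (percentile 97.97). JUN, a member of this list, had 1.36% in ABE8e. The 9 measured cytosolic chaperone and heat shock genes had a median of 2.22% in ABE8e and 1.23% in ABE8eW, both at percentile 100, and 1.54% in ABE8s, at percentile 99.9. Members differed widely: DNAJB1 had 7.29% in ABE8e, HSPA1B, which shares reads with a near-identical copy, 0.949%, HSPE1 0.501% and HSP90AA1 0.281%. In ABE8eWQ and ABE8sQ the chaperone list lay at percentiles 95.1 and 80.0.

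The 12 measured translation factors had a median of 0.994% in ABE8e (percentile 98.4) and 1.19% in ABE8s (percentile 96.8), with 1.44% for EEF2 and 0.640% for EEF1A1 in ABE8e. The 5 measured genes of the unfolded protein response lay low, with a median of 0.388% in ABE8s at percentile 1.40 and 0.312% in ABE8e at percentile 7.82. HSPA5 and HSP90B1 carried 0.312% and 0.209% in ABE8e, whereas XBP1 carried 3.06%. The 58 measured nuclear-encoded oxidative phosphorylation subunits had a median of 0.672% in ABE8s at percentile 0.73 and 0.526% in ABE8e at percentile 20.8. ATP5F1B, a subunit of ATP synthase, carried 1.28% in ABE8e and NDUFB10, a subunit of complex I, 0.597%. The 75 measured ribosomal protein genes lay at percentile 23.8 in ABE8e and 23.5 in ABE8s, with medians of 0.549% and 0.842%.

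Most of the remaining lists lay inside the middle 95% of random lists in ABE8e. The percentiles there were 43.5 for the 3 measured ADAR recoding targets (COPA 1.83%), 26.1 for 8 histones (H2AX 1.92%, H2AZ1 0.217%), 37.9 for 5 proto-oncogenes (NRAS 0.234%), 82.0 for 6 tumour suppressors (SMAD4 1.19%), 79.9 for 7 glycolysis genes (PGK1 0.9503%), 80.7 for 9 splicing factors (SF3A1 1.61%) and 61.1 for 5 repair genes (XRCC1 1.82%). Elsewhere, the proto-oncogenes lay at percentile 1.98 in ABE8eW with a median of 0.149%, and the ADAR targets at percentile 97.6 in ABE8sQ with a median of 0.0942%. With 5 libraries and many lists, some values outside the middle 95% arise by chance. Of p53 targets 1 gene was measured (SESN2) and of the listed long non-coding RNAs 2 (NORAD and KCNQ1OT1). Interferon response, tRNA and RNA deaminase and mitochondrially encoded lists had 0 measured members, and so did the fibroblast, leukocyte, hepatocyte and keratinocyte markers. Among the markers seen at all, the highest mean depth was 4.05, for LYZ in ABE8e.

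Single adenosines reached majority G. In PPP1R15A, position 1808 of NM_014330.3 (GRCh38 chromosome 19, 48874772, plus strand, exon 2, a synonymous site of codon 513) carried G in 62.2% of 378 reads in ABE8e, 61.8% of 429 in ABE8s and 2.68% of 299 in ABE8eWQ. It carried 0% of 136 in nCas9 and 0% of 279 in ABE8sQ. In HMOX1, position 488 of NM_002133.3 (chromosome 22, 35386950, exon 3) changes tyrosine codon 137 from UAC to the cysteine codon UGC. It carried G in 58.3% of 374 reads in ABE8e, 48.7% of 347 in ABE8eW, 10.99% of 446 in ABE8eWQ, 44.7% of 559 in ABE8s and 1.78% of 393 in ABE8sQ, against 0% of 210 in nCas9. Tyrosine UAC codons were also hit in DUSP1 (chromosome 5, 172769763, minus strand, exon 3, codon 182), with 48.8% in ABE8e, and in DNAJB1 (chromosome 19, 14518195, minus strand, exon 1, codon 52), with 37.9%. In HSPA6 (chromosome 1, 161525457) a threonine-to-alanine site in codon 267 carried 46.1% of 1477 reads. Sites in the 3′ UTRs of TNFRSF12A (chromosome 16, 3022263) and IER2 (chromosome 19, 13154355) carried 39.4% and 39.2%. SNHG15 (chromosome 7, 44984362) carried 43.8% and BRF2, a lysine-to-glutamate site in codon 252 (chromosome 8, 37844996), 38.2% of 55 reads.

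Across the 297 HMOX1 adenosines with at least 50 reads in each library, a floor set for this profile after seeing the data, 66 carried at least 10% G in ABE8e. The count was 49 in ABE8eW, 1 in ABE8eWQ, 30 in ABE8s and 0 in both nCas9 and ABE8sQ. Edited positions lay along the whole mRNA, in the coding part from position 79 to 945 and on both sides of it.

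**Figure D1:**
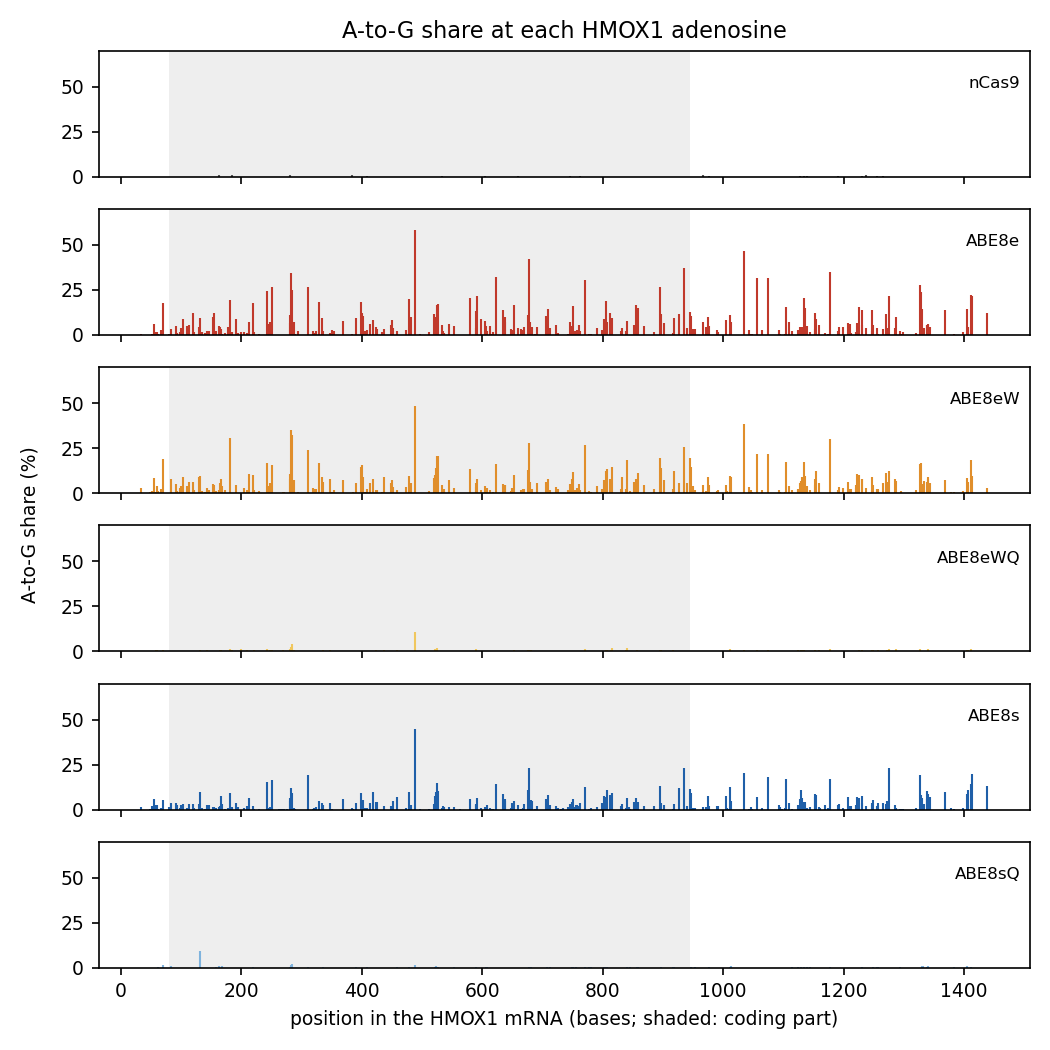
A-to-G share in percent at each of 297 HMOX1 adenosines along the mRNA in the 6 libraries, 1 panel per library on the same linear scale, with the coding part shaded. The highest bar is position 488, at 58.3% in ABE8e and 10.99% in ABE8eWQ, and no bar in nCas9 exceeds 1.07%.

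The highest sites of the Q libraries were lower. HSPA6 position 1168 (chromosome 1, 161525707, lysine to arginine in codon 350) carried 12.6% of 350 reads in ABE8eWQ and 4.66% of 1630 in ABE8sQ, against 0% of 807 in nCas9. In ABE8sQ, LAP3 (chromosome 4, 17584992, exon 6) carried 13% of 423 reads at a glutamine-to-arginine site in codon 187. That site carried 7.81% in ABE8e, 0.481% in ABE8eWQ and 7.39% in ABE8s. SNRNP200 (chromosome 2, 96274831, 3′ UTR) carried 12.2% of 441 reads in ABE8sQ and 11.01% in ABE8s, and SHISA9 (chromosome 16, 13239344, 3′ UTR) carried 14.3% of 63 reads in ABE8sQ. Other leading sites of ABE8s were DUSP1 codon 187 (chromosome 5, 172769748, tyrosine UAU to cysteine) at 50.5% and the 3′ UTR of YRDC (chromosome 1, 37803261) at 45.2%. A site of PPP1R15A codon 391 (chromosome 19, 48874405, tyrosine UAU to cysteine) carried 55.1% in ABE8eW.

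The V106W comparison set ABE8eW against ABE8e. In ABE8eW, 2655 of 2936 genes had a lower share than in ABE8e. After background subtraction, ABE8eW held 0.559 of the ABE8e excess (0.551 to 0.567, gene resampling), so 44.1% of the excess was lost, and it was lower on 23 of 23 chromosomes. The largest falls were in EPB41L4A-AS1, from 5.76% to 2.58%, DNAJB1, from 7.29% to 4.38%, IER2, from 7.06% to 4.48%, SELENOW, from 4.80% to 2.29%, and MERTK, a receptor tyrosine kinase, from 3.37% to 0.940%. TNFRSF12A changed little, from 6.70% to 6.59%. The largest rises in ABE8eW, in genes with 5965 to 11523 reads per library, were in RRAGC (0.992% against 0.204%), ZNF576 (1.43% against 0.674%), PMAIP1 (1.40% against 0.740%), GOLPH3 (1.08% against 0.473%) and NID1 (0.943% against 0.352%). Counted by edited adenosines after subtraction of the nCas9 count, the ratio of ABE8eW to ABE8e was 0.378, over 1.4 times lower than by reads.

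The Q comparisons set ABE8eWQ against ABE8eW and ABE8sQ against ABE8s. ABE8eWQ was lower in 2882 of 2936 genes and ABE8sQ in 2925. The Q form kept 0.0556 of the ABE8eW excess (0.0532 to 0.0578) and 0.039 of the ABE8s excess (0.0354 to 0.0428), falls of 18.0-fold and 25.6-fold. Both were lower on 23 of 23 chromosomes. The nCas9 share was subtracted unscaled. Substitution types other than A-to-G and C-to-T lay at 0.908 to 0.991 times nCas9 in ABE8eWQ and at 0.854 to 0.949 times in ABE8sQ. The retained fractions may therefore be somewhat understated, which their intervals do not cover. SESN2 went from 6.98% in ABE8eW to 0.29% in ABE8eWQ and from 5.91% in ABE8s to 0.17% in ABE8sQ, and EGR1 went from 6.92% in ABE8s to 0.129% in ABE8sQ. SRP19, a subunit of the signal recognition particle, went from 6.92% in ABE8s to 0.321%, below its nCas9 share of 0.402%. Among the genes with the largest rise with Q were ZNF587B (0.532% in nCas9, 0.297% in ABE8eW, 0.707% in ABE8eWQ) and SOX2 (0.0207% in nCas9, 0.0149% in ABE8s, 0.0656% in ABE8sQ). The Wilson interval of ZNF587B in ABE8eWQ (0.538 to 0.929) lay above that in ABE8eW (0.207 to 0.426) but overlapped that in nCas9 (0.388 to 0.729). SOX2 had 6237 to 9657 reads per library, and its intervals in ABE8s (0.00263 to 0.0843) and ABE8sQ (0.028 to 0.153) overlapped, so its rise lay within counting error.

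Some residual editing remained in both Q libraries. The largest ABE8sQ minus nCas9 differences were in TIGD1, LRRC57, ZNF576, RPL21 and LINC01521. TIGD1 (1.62% in ABE8sQ) and LRRC57 (0.521%) already carried 1.21% and 0.253% in nCas9, so part of their share was background. LINC01521 carried 0.312% in ABE8sQ against 0.068% in nCas9. It was not lower than in ABE8s (0.266%), with overlapping Wilson intervals. RPL21, a ribosomal protein gene with many pseudogenes, carried 0.294% in ABE8sQ over at least 1337694 reads per library, against 0.0384% in nCas9. In ABE8eWQ, SNHG15 carried 0.41%, TNFRSF12A 0.386% and BBS5 0.525%, and BBS5 already carried 0.207% in nCas9. The retained fraction depended on the processing. For ABE8eWQ over ABE8eW it was 0.110 with no site left out and 0.0141 by edited adenosines after subtraction of the nCas9 count. For ABE8sQ over ABE8s it was 0.00929 by the same count. These counts were nets of gains and losses of similar size. In ABE8eWQ, 1059 adenosines were edited that were not in nCas9, and 977 the other way. The numbers for ABE8sQ were 1152 and 969. The fractions by count carry no interval and are uncertain.

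The editors without W or Q also differed. ABE8s held 1.36 times the excess of ABE8e (1.29 to 1.43), was higher on 22 of 23 chromosomes, and was higher in 2073 of 2936 genes. The direction was the opposite in SESN2, DNAJB1, HMOX1 and IER2, whose shares were larger in ABE8e. ABE8sQ held 1.70 times the excess of ABE8eWQ (1.53 to 1.90), but 1.11 times with no site left out.

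Sequence context separated the editors. After a 5′ U, the A-to-G share was 0.0215% in nCas9, 1.89% in ABE8e, 0.769% in ABE8eW, 0.0478% in ABE8eWQ, 2.87% in ABE8s and 0.0546% in ABE8sQ. After a 5′ A it was 0.0284%, 0.304%, 0.247%, 0.0579%, 0.699% and 0.106% in the same order. The excess after U was 6.79 times that after A in ABE8e, 3.42 times in ABE8eW and 4.25 times in ABE8s, but 0.891 times (0.861 to 0.92) in ABE8eWQ and 0.429 times (0.419 to 0.438) in ABE8sQ. Adenosines after U took 37.4% of the excess G reads in ABE8e, 26.4% in ABE8eW, 16.7% in ABE8eWQ, 41.0% in ABE8s and 12.2% in ABE8sQ. They held between 13.4% and 13.7% of the reads. Counted over the 1152 adenosines edited in ABE8sQ and not in nCas9 the part was 18.3%, but 969 were edited in nCas9 and not in ABE8sQ, so most of this set could be background. In single genes, the excess was larger after A than after U in 6 of 2032 genes in ABE8e, 44 in ABE8eW, 1056 in ABE8eWQ, 3 in ABE8s and 1505 in ABE8sQ. Of 16 contexts of 3 bases, UAC was highest in ABE8e at 2.38% and UAU in ABE8s at 3.18%, while AAG was highest in ABE8sQ at 0.112%.

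By transcript region, ABE8e edited the coding part at 0.801%, the 5′ UTR at 0.674% and the 3′ UTR at 0.618%. ABE8s reached 1.21% in the 3′ UTR, 0.955% in the coding part and 0.645% in the 5′ UTR. The shares in nCas9 were 0.0376%, 0.0199% and 0.0533% for the coding part, the 5′ UTR and the 3′ UTR. In the coding part, 0.824% of reads at missense adenosines and 0.712% at synonymous ones carried G in ABE8e.

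Tyrosine codons were the most affected group of amino acid codons in ABE8e. Their second base, whose change gives cysteine, carried G in 2.27% of reads at UAU and 2.81% at UAC in ABE8e, 0.855% and 1.24% in ABE8eW, and 3.07% and 2.87% in ABE8s. In ABE8eWQ the shares were 0.0383% and 0.067%, and in ABE8sQ 0.0422% and 0.0549%, against 0.014% and 0.0164% in nCas9. Together the tyrosine-to-cysteine sites had 2.59% in ABE8e, the highest of all amino acid changes there, while in ABE8s isoleucine-to-methionine sites had 3.28% and synonymous valine sites 3.51%. At stop codons, the second base of UAA carried 1.72% in ABE8e and 2.95% in ABE8s, and that of UAG 1.72% and 2.80%. The last base of UGA carried 0.525% and 0.748%. Adenosines of the start codon carried 0.647% in ABE8e and 0.645% in ABE8s, against 0.0104% in nCas9.

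Cytosine catalysis, the topic of the series title, was examined as C-to-T change at 1451335 cytidines. The C-to-T share was 0.0211% in nCas9, 0.0227% in ABE8e, 0.0215% in ABE8eW, 0.0212% in ABE8eWQ, 0.0223% in ABE8s and 0.0207% in ABE8sQ. Relative to nCas9 these were 1.08-fold, 1.02-fold, 1.007-fold, 1.06-fold and 0.984-fold. The 10 types other than A-to-G and C-to-T lay between 0.854 and 1.06 times nCas9 in the editor libraries, apart from G-to-T in ABE8e at 1.245. The C-to-T ratio of ABE8e exceeded all of these but G-to-T of the same library, and those of the other editors did not exceed 1.06. Within its own library, however, the C-to-T ratio of each other editor lay above all 10 other types. It was 1.056 in ABE8s against at most 0.9951, and 1.018 in ABE8eW against at most 1.001. In ABE8eWQ it was 1.007 against at most 0.9913, and in ABE8sQ 0.9836 against at most 0.9486. After a 5′ U the C-to-T share was 1.19-fold that of nCas9 in ABE8e (1.17 to 1.21) and 1.18-fold in ABE8s (1.15 to 1.199). After the other bases it was 1.05-fold and 1.03-fold. The folds after U were 1.07 in ABE8eW, 1.03 in ABE8eWQ and 1.02 in ABE8sQ. With no site left out, the overall folds rose to 1.60, 1.28, 1.48, 1.33 and 1.27 in the order ABE8e, ABE8eW, ABE8eWQ, ABE8s and ABE8sQ. As an unweighted mean of sites the nCas9 C-to-T share was 0.0347%, and with no site left out it was 0.0762%. At a minimum of 50 reads ABE8eW and ABE8eWQ fell below nCas9, to 0.998 and 0.987.

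Gene coverage was used as a measure of transcript abundance, in 2474 genes. PPP1R15A was higher than in nCas9 in all 5 editor libraries, by 1.65 on the log2 scale in ABE8e, 1.32 in ABE8eW, 1.45 in ABE8eWQ, 1.81 in ABE8s and 1.16 in ABE8sQ. BAG3 stood at 1.56, 1.32, 1.03, 2.56 and 2.02 in the same order, and LINC01873, a long non-coding RNA, between 1.47 and 1.81. DNAJB1 stood at 2.12 in ABE8s and 1.84 in ABE8sQ but 0.35 in ABE8eWQ, and HSPA6 at 1.74 in ABE8s and -1.03 in ABE8eWQ. The chaperone list of 7 genes had medians of 0.33 in ABE8e, 0.38 in ABE8eW, 0.60 in ABE8s and 0.34 in ABE8sQ, at percentiles from 99.6 to 100. In ABE8eWQ it was 0.04 (percentile 75.9), no further from 0 than the median of all genes there, 0.05. Against the mean of the other 4 editors it was 0.30 in ABE8s and 0.11 in ABE8sQ, but -0.11 in ABE8e, -0.01 in ABE8eW and -0.29 in ABE8eWQ. Immediate early genes had a median of 0.50 in ABE8s (percentile 99.1) and 0.35 in ABE8sQ (percentile 97.2), but against the mean of the other 4 editors 0.37 and 0.06. In the other editors their percentiles against nCas9 lay between 43.4 and 88.0. The 4 measured genes of the unfolded protein response had medians of 0.56 in ABE8e and 0.55 in ABE8s (percentiles 99.9 for both). HSPA5 stood at 0.69 and 0.52, but SDF2L1 at -0.18 and 0.07. Against the mean of the other 4 editors the list had 0.26 in ABE8e and 0.30 in ABE8s, but -0.05 in ABE8eW, -0.33 in ABE8eWQ and -0.11 in ABE8sQ.

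Oxidative phosphorylation subunits were lower than in nCas9 in all 5 editor libraries, with medians from -0.31 to -0.25 at percentile 0, for instance COX6A1 at -0.23 in ABE8e. All 5 ratios share the single nCas9 library, and against the mean of the other 4 editors the medians lay between -0.04 and 0.05. An effect common to the editors therefore cannot be told from a deviation of that library. Ribosomal proteins had medians from -0.24 to -0.15, at percentiles from 0.055 to 4.86, and from -0.04 to 0.04 against the other editors. The random lists were matched on reads and not on transcript length. Coverage ratios to nCas9 rose with length in all 5 editor libraries (Spearman rho from 0.127 to 0.228). How far length enters the percentiles of these lists was not tested. MIR4484 fell by 3.55 in ABE8e alone, and CALCB was lower in all 5 editors, from -0.99 to -0.74. PRRC2A, CLTC and LIN28B were among the highest genes in ABE8eWQ, at 1.71, 1.55 and 1.52. They were higher than in nCas9 in all 5 editors, from 1.49 to 1.71, from 1.29 to 1.62 and from 1.26 to 1.52.

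At least 2-fold higher coverage than in nCas9 was seen for 16 genes in ABE8e, 21 in ABE8eW, 42 in ABE8eWQ, 30 in ABE8s and 44 in ABE8sQ, and 2-fold lower coverage for 3, 0, 1, 2 and 1. Scaled by the median ratio over genes, the higher counts were 15, 20, 29, 29 and 40, so the count of ABE8eWQ was no longer above that of ABE8s. Against the mean of the other 4 editors, an alternative chosen after seeing the data, the higher counts were 0, 1, 2, 3 and 0. Most of these differences were therefore no longer 2-fold with that reference. It removes by construction what the editors share, so an effect common to the editors cannot be told from a deviation of the nCas9 library. The exceptions in ABE8s were HSPA6, DNAJB1 and BAG3, which stayed higher than the other editors by 1.64, 1.25 and 1.08. Coverage also moved with transcript length: genes with transcripts of 3000 bases or more had medians from 0.09 to 0.16, and genes under 1000 bases from -0.04 to -0.01.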

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

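The tests on variants or paralogs, carried-over reads, sequencing errors in ABE8sQ, a changed preference with Q and overall errors at cytidines were chosen after the result was seen. The test on GC content was added after the first results, with its bound fixed before it was run, and the AUUUA test within classes of similar GC content was added last. All patterns were found and tested in the same 6 libraries.

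Some signals above nCas9 lay outside the A-to-G and C-to-T comparisons or outside the gene shares. C-to-A reached 0.00538% in ABE8e against 0.00508% in nCas9, and G-to-T 0.00744% against 0.00598%. ABE8eW, ABE8s, ABE8eWQ and ABE8sQ stayed at or below 0.00508% for C-to-A and 0.00586% for G-to-T, so these excesses were seen in the ABE8e library alone. An RPL10A transcript without a gene name in the gene table carried A-to-G at adenosines located in introns of the protein-coding transcripts. The share there was 10.1% in ABE8e, 9.27% in ABE8eW, 0.756% in ABE8eWQ, 8.10% in ABE8s and 0.855% in ABE8sQ, against 0.0481% in nCas9.

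Immediate early and heat shock transcripts such as IER2, DUSP1, EGR1, DNAJB1 and HSPA6 were among those with high A-to-G shares, although SESN2 stood above them in ABE8e and members such as HSP90AA1 (0.281%) and HSPE1 (0.501%) lay below the median gene (0.599%). Neighbouring bases did not account for this, since the median of observed over expected excess of the 14 members was 3.47 in ABE8e, at percentile 100, and variants or paralogs would have shown in nCas9, where their median was 0.0450% against 2.65% in ABE8e. Of random lists matched on GC content, the middle 95% ended at 1.503, below the 3.47 of the members. Synthesis of short-lived transcripts after the editor was expressed was tested through AUUUA elements in other genes, where genes with 4 or more had a lower ratio than genes with none (difference -0.591, interval -0.748 to -0.415). The rule fixed before this test counted such a value against the explanation, but it did not hold GC content, which rose with the ratio across genes (rho 0.456). Within 2 classes of similar GC content the differences were -0.250 and -0.142, also below 0. The interval of their mean, -0.432 to 0.220, held 0, with 85 genes against 113. These values gave no sign of a contribution but could not exclude one, so this explanation stays open.

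The excess of ABE8sQ was highest after a 5′ A, whereas that of ABE8s was highest after a 5′ U. Reads carried over from ABE8s as the whole source would have kept the preference for U, but the ratio of U to A was 0.429, and the other substitution types of ABE8sQ had a median of 0.911 times nCas9, which argues against more sequencing errors. A few abundant transcripts did not make the pattern, since 74.1% of 2032 genes (72.1 to 75.9) showed it. A changed preference of the deaminase with Q is a candidate explanation, since the ratio of U to A also fell from ABE8eW to ABE8eWQ, by 3.84-fold. A shift that comes with a lower amount of editor was not tested.

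The C-to-T share after a 5′ U was above nCas9 in ABE8e and ABE8s. A general rise of errors would move all contexts alike, but the ratio to nCas9 in ABE8e was 1.191 after U (1.17 to 1.21) and 1.05 after the other bases. Deamination of cytidines by the editor may contribute, since the excess after U in the tenth of genes with the highest A-to-G excess was 0.00699% against 0.00324% in the other genes of ABE8e, and 0.00699% against 0.00282% in ABE8s. In ABE8s the excess after the other bases rose too, to 0.00173% (0.000831 to 0.00263) against 0.000271% (0.0000370 to 0.000506), so the rise there was not particular to U, while in ABE8e it was 0.00115% against 0.000931%. Each editor's own A-to-G ranking chose these genes, and other properties of highly edited transcripts were not tested.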

How the results depend on the processing

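The A-to-G and C-to-T shares, the V106W and Q ratios, the counts of edited adenosines, the part of the excess after a 5′ U and the counts of genes with 2-fold coverage were recomputed under other settings, while single genes, sites, regions, codons and editing of gene lists were not. The settings were chosen before any result except for the comparison of coverage with the other editors, chosen after seeing the data. The A-to-G shares kept their order, from nCas9 through ABE8eWQ, ABE8sQ, ABE8eW and ABE8e to ABE8s, in 7 of 7 settings. The V106W and Q ratios stayed below 1 in every setting run. The counts of edited adenosines kept the same order in 6 of 8 settings. At 50% G, ABE8e stood above ABE8s, and without thinning ABE8eWQ (1427) stood above ABE8sQ (1355). The order of the C-to-T shares was the same in 1 of 6 settings. ABE8e was highest in every setting, and ABE8s came next except with no site left out. The order of the other libraries changed, so no ranking among those by C-to-T can be read from them.

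A minimum of 20 reads gave A-to-G shares of 0.0404% in nCas9, 0.727% in ABE8e, 0.425% in ABE8eW, 0.0617% in ABE8eWQ, 0.972% in ABE8s and 0.0770% in ABE8sQ. Its counts of edited adenosines were 499 in nCas9, 8588 in ABE8e, 2992 in ABE8eW, 532 in ABE8eWQ, 11325 in ABE8s and 552 in ABE8sQ, and its C-to-T shares were 0.0206% in nCas9, 0.0221% in ABE8e, 0.0208% in ABE8eW, 0.0206% in ABE8eWQ, 0.0216% in ABE8s and 0.0202% in ABE8sQ. Raised to 50 reads, the A-to-G shares were 0.0392% in nCas9, 0.727% in ABE8e, 0.425% in ABE8eW, 0.0604% in ABE8eWQ, 0.972% in ABE8s and 0.0763% in ABE8sQ. The edited adenosines numbered 79 in nCas9, 3085 in ABE8e, 853 in ABE8eW, 97 in ABE8eWQ, 4635 in ABE8s and 107 in ABE8sQ, and the C-to-T shares were 0.0200% in nCas9, 0.0212% in ABE8e, 0.0199% in ABE8eW, 0.0197% in ABE8eWQ, 0.0208% in ABE8s and 0.0194% in ABE8sQ. The V106W ratio was 0.561 and the Q ratio on ABE8s 0.0397. The counts fell because fewer sites reach the minimum and because at low depth 2 G reads already make 10%, so depth limits how far these counts can be compared with other data.

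With no site left out, the A-to-G shares were 0.0825% in nCas9, 0.796% in ABE8e, 0.480% in ABE8eW, 0.126% in ABE8eWQ, 1.03% in ABE8s and 0.131% in ABE8sQ. The V106W ratio was 0.557, the Q ratio on ABE8eW 0.110 and the Q ratio on ABE8s 0.0512. The C-to-T shares were 0.0762% in nCas9, 0.122% in ABE8e, 0.0978% in ABE8eW, 0.113% in ABE8eWQ, 0.102% in ABE8s and 0.0967% in ABE8sQ. Sites with 10% or more of the changed base in all 6 libraries enter here by construction, and they raise both shares. Leaving out sites with 1% or more G in nCas9 gave 0.0308% in nCas9, 0.725% in ABE8e, 0.421% in ABE8eW, 0.0578% in ABE8eWQ, 0.970% in ABE8s and 0.0731% in ABE8sQ. The ratios were 0.563 for V106W, 0.0691 for Q on ABE8eW and 0.0451 for Q on ABE8s. This selection lowers nCas9 by construction, so the excess of the Q libraries over nCas9 is overstated in it.

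On each library's own sites, the A-to-G shares were 0.0423% in nCas9, 0.731% in ABE8e, 0.428% in ABE8eW, 0.0636% in ABE8eWQ, 0.977% in ABE8s and 0.0787% in ABE8sQ, and the C-to-T shares were 0.0217% in nCas9, 0.0241% in ABE8e, 0.0228% in ABE8eW, 0.0222% in ABE8eWQ, 0.0233% in ABE8s and 0.0218% in ABE8sQ. Without the positions near exon boundaries, the A-to-G shares were 0.0421% in nCas9, 0.0633% in ABE8eWQ, 0.981% in ABE8s and 0.0786% in ABE8sQ, with the C-to-T shares at 0.0213% in nCas9, 0.0230% in ABE8e, 0.0217% in ABE8eW, 0.0216% in ABE8eWQ, 0.0225% in ABE8s and 0.0210% in ABE8sQ. As unweighted means of sites, the A-to-G shares were 0.0642% in nCas9, 0.743% in ABE8e, 0.444% in ABE8eW, 0.0835% in ABE8eWQ, 0.974% in ABE8s and 0.0918% in ABE8sQ. The Q ratios were 0.0507 on ABE8eW and 0.0303 on ABE8s, and the C-to-T shares were 0.0347% in nCas9, 0.0374% in ABE8e, 0.0359% in ABE8eW, 0.0345% in ABE8eWQ, 0.0360% in ABE8s and 0.0346% in ABE8sQ. The cause of the shifts under these settings was not tested.

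As ratios of edited adenosines after subtraction of the nCas9 count, the V106W comparison gave 0.378, Q on ABE8eW 0.0141 and Q on ABE8s 0.00929. Over all settings the fall with V106W lay between 43.7% and 62.2% of the excess, that with Q on ABE8eW between 89.0% and 98.6%, and that with Q on ABE8s between 94.9% and 99.1%. The upper ends came from the ratios of edited adenosines. For Q these rest on small nets of gains and losses, carry no interval and are uncertain. At a threshold of 5% G the edited adenosines numbered 2499 in nCas9, 43500 in ABE8e, 18556 in ABE8eW, 2805 in ABE8eWQ, 58834 in ABE8s and 3002 in ABE8sQ. At 20% G there were 345 in nCas9, 3539 in ABE8e, 1479 in ABE8eW, 363 in ABE8eWQ, 3990 in ABE8s and 365 in ABE8sQ. At 50% G there were 12 in nCas9, 118 in ABE8e, 35 in ABE8eW, 12 in ABE8eWQ, 101 in ABE8s and 14 in ABE8sQ. On each library's own sites without thinning there were 2435 in nCas9, 27586 in ABE8e, 13716 in ABE8eW, 2571 in ABE8eWQ, 34559 in ABE8s and 3125 in ABE8sQ. Fisher's exact test against nCas9 gave 49848 in ABE8e, 22883 in ABE8eW, 311 in ABE8eWQ and 72534 in ABE8s. At 50% G, nCas9 and ABE8eWQ were tied. A change of threshold moves these counts by construction.

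Counted over adenosines edited in the editor and not in nCas9, instead of over reads, the share after a 5′ U was 44.8% in ABE8e, 29.4% in ABE8eW, 20.2% in ABE8eWQ, 61.2% in ABE8s and 18.3% in ABE8sQ, in the same order of libraries as by reads. These numbered 1059 in ABE8eWQ and 1152 in ABE8sQ, while 977 and 969 were edited in nCas9 and not in the respective Q library, so the shares of these libraries said little about the editors. Against the mean of the other 4 editors, the genes with 2-fold higher coverage numbered 0 in ABE8e, 1 in ABE8eW, 2 in ABE8eWQ, 3 in ABE8s and 0 in ABE8sQ, and those with 2-fold lower coverage 1 in ABE8e, 0 in ABE8s and 0 in ABE8sQ. Scaled by the median ratio over genes, 2 genes were 2-fold lower in ABE8eWQ, and the genes with 2-fold higher coverage numbered 15 in ABE8e, 20 in ABE8eW, 29 in ABE8eWQ, 29 in ABE8s and 40 in ABE8sQ, against 42 in ABE8eWQ and 30 in ABE8s without it. The change of reference from nCas9 to the other editors removes by construction what the editors share.

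No paired analysis was possible because the labels give 1 library per group and no pairing. Editor expression was not measured, so the size of each difference between editors rests on single cultures. Reads shared among isoforms or copies of a gene were placed before deposition, and their placement could not be varied here.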

Other observations

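The UAC thresholds and the match of the RPL10A transcript to the annotation were chosen after the result was seen.

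RPL10A, which encodes a protein of the large ribosomal subunit, was covered by an ordinary mRNA and by a second transcript, XM_017010900.1. The second transcript was the same at 958 of 961 positions as a GENCODE transcript without a coding part, ENST00000478340.2 (GRCh38 chromosome 6, 35468420 to 35470781, plus strand). Its position 415 carried G in 57.4% of 277 reads in ABE8e, 60.5% of 220 in ABE8eW, 10.76% of 158 in ABE8eWQ, 50.5% of 521 in ABE8s and 15.7% of 261 in ABE8sQ, against 0% of 236 in nCas9. In the adenosines shared with the exons of the coding transcripts, the share was 16.4% in ABE8e and 11.1% in ABE8s, while RPL10A as a gene carried 0.979% and 1.30%.

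Non-coding transcripts of other coding genes differed from the mRNAs in both directions. Those of the RNA-binding protein genes HNRNPDL and SRSF3 carried 3.19% and 3.49% in ABE8e, against 0.346% and 0.406% for the mRNAs, and that of DCAF7 6.00% against 0.342%, while those of FMC1 and SARS1 carried 0.0889% and 0.392%, against 1.09% and 1.83%. A general excess over non-coding transcripts may exist but was not shown: they had the higher share in 23 of 39 genes, 58.97% with an interval from 43.4 to 72.9 that held 50%. The rule fixed before this test counted such an interval against the explanation, and 39 genes were too few to exclude it.

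Adenosines of the same UAC context were edited to very different levels within 1 transcript. In 17 of 21 transcripts, 80.95% (60 to 92.3), the adenosines with 20% or more G had a higher mean predicted unpaired probability, in windows of 81 bases, than those with 2% or less. The medians were 0.951 over 45 adenosines and 0.882 over 67. A higher predicted unpaired probability is therefore a candidate source of the difference, although the medians of both sets were high. Loops were not identified as such, and the prediction was made without the cellular proteins that bind RNA.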
